A study of Mus musculus domesticus with 12 samples.

How the data were processed

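Transcripts were measured in erythroid cells cultured from mouse fetal liver, in 3 groups of 4 libraries each. The groups differed in the short hairpin RNA (shRNA) carried by the retrovirus: firefly luciferase as control (shLuc), Dis3 (shDis3) or Exosc10 (shExosc10). Group and replicate number were taken from the sample titles. The labels do not say whether the replicates of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

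Per the labels' protocols, RNA was extracted with Trizol from sorted cells and libraries were made with a stranded kit for picogram amounts of total RNA. Such a kit keeps non-polyadenylated RNA and nuclear RNA, and its libraries can carry signal from residual genomic DNA. The submitters' processing notes name STAR 2.5.3a, RSEM 1.3.0 and the mouse genome build GRCm38 (mm10), without roles or order. The annotation release, the strand setting and any filters are not given in the sources used here. Per the file headers, the authors deposited gene tables with an RSEM expected count for each gene, which is an estimated read count that splits ambiguous reads between genes and need not be whole. The deposited tables also gave TPM, which is scaled to the same total in each library, and an effective length in bases, which was not used. Before rounding, 4.5% of the gene counts were not whole. Counts of near-identical genes, such as the globin pairs, the clustered histone genes, pseudogenes and small RNA families, depend on how RSEM divided shared reads and are uncertain. Counts of overlapping and antisense genes are uncertain for the same reason, since the strand setting is not known.

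Gene symbols, types and coordinates came from GENCODE mouse release M21 on the same build. Of 55385 identifiers, 54487 matched with their version and 55144 without it. Library totals lay between 14936232 and 32397207 counts. No pair of libraries was close enough to be the same library deposited more than once: the lowest chi-square per degree of freedom over genes with a summed count of at least 10 was 13.1 over all pairs, and 16.0 to 319.2 within groups. Intervals from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

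The expected counts were rounded to whole numbers and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default filter on low counts by group and all 12 libraries in a model with group as the only term. This left 17651 genes, a biological coefficient of variation of 60% and 5.45 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Normalised CPM used the library sizes scaled by TMM and are given as mean ± SD over 4 libraries. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

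The test was checked on simulated counts drawn for the real genes, with 200 genes changed per knockdown and 15771 genes left by the filter. Of genes changed 2-fold, 40.3% were recovered for shDis3 against shLuc, 37.3% for shExosc10 against shLuc and 52.2% for shDis3 against shExosc10. At 4-fold these shares were 95.5%, 94.0% and 95.5%, and at 8-fold 100%, 98.5% and 99.2%. Only genes with a mean of at least 5 CPM were changed, and the simulated libraries held no clusters. The planted changes gave 171, 160 and 351 calls in all, which eases the adjusted threshold. These shares can therefore overstate recovery in the data, where Dis3 in shDis3 against shLuc missed the threshold.

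In all, 36 gene lists with at least 5 measured members were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with a correlation estimated from the residuals, and with fry. The lists were exosome subunits, exosome adaptors and cofactors, snoRNA host genes, snoRNAs and scaRNAs, other structured small RNAs, histone genes of the clusters, p53 targets, apoptosis regulators, DNA damage repair and checkpoint, erythroid transcription factors, heme synthesis and iron uptake, globins, red cell membrane and maturation genes, stem and early progenitor genes, granulocyte markers, macrophage and monocyte markers, megakaryocyte markers, mast cell and basophil markers, lymphoid markers, hepatocyte markers, endothelial and stromal markers, interferon-stimulated genes, integrated stress and ATF4 targets, immediate early and heat shock genes, NF-kB and inflammatory genes, ribosomal protein genes, ribosome biogenesis, S phase genes, G2 and M phase genes, autophagy and mitochondrial clearance, erythropoietin and STAT5 response, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs and sex-linked marker genes. Annotated RNA classes formed a separate family of 6, in which no miRNA gene passed the filter. A list score is the mean log2 CPM of the members with a prior count of 2, centred over the 12 libraries. Scores were compared with a two-sided exact permutation test of 4 against 4 libraries, whose smallest p is 0.029. The target of an shRNA was left out of the lists in its comparisons.

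Genes were named by rule: both targets, up to 6 rises and 6 falls among called genes with a mean of at least 5 CPM, a real symbol and no overlap between groups, and per described list up to 4 called members or otherwise the 2 with the highest mean CPM. Other named genes are said to be chosen after their values were seen. Similarity of fold changes between the knockdowns was compared with 100 simulated draws of unchanged groups against the shared controls, and with the controls split in all 6 ways.

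Alternatives were RLE and upper-quartile factors, no filter, a filter of 5 mean CPM, DESeq2 1.42.0, limma on log2(TPM + 1), only the 8 libraries compared, replicate number as a block, protein-coding nuclear genes only, a robust spread estimate, a test against a log2 fold change of 0.5, and leaving out each library. Added after the data were seen were fits without 3 libraries whose best correlation with their own group was under 0.95, without 4 libraries that shared a cluster with no other library of their group, and with that cluster of libraries as a factor. Clusters came from average linkage of the correlations of log2 CPM at 0.97, both bounds also set after the data were seen. As the clusters came from the expression values being tested, these fits are descriptive. Figures and joins used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.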

Results

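The RNA exosome is a protein complex that trims and degrades RNA, and Dis3 and Exosc10 are its catalytic subunits. The series addressed how the transcriptome of erythroid precursors depends on each of them. Lineage-depleted liver cells of C57BL/6J mouse embryos at embryonic stage E14.5 were infected with retroviruses that carried an shRNA and the marker GFP. After 2 days in a medium that expands erythroid cells, GFP-positive cells with intermediate or positive CD71 (the transferrin receptor) and no Ter119 (a marker of later erythroblasts) were sorted. These are erythroid precursors and proerythroblasts. Total RNA was sequenced from 4 libraries per group. Total counts were 22149787, 27910398, 22168454 and 28177503 in shLuc replicates 1 to 4, 25723200, 14936232, 32397207 and 30693623 in shDis3, and 29165525, 24849164, 29958493 and 19337791 in shExosc10.

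The targeted transcripts were low in every library that carried the matching shRNA. Dis3 (ENSMUSG00000033166.11, chromosome 14, 99075206 to 99099770, minus strand) measured 131.3 ± 20.32 CPM in shLuc, 38.26 ± 12.06 in shDis3 and 143.1 ± 35.91 in shExosc10 (SD, n = 4). Exosc10 (ENSMUSG00000017264.16, chromosome 4, 148558429 to 148582401, plus strand) measured 98.19 ± 12.02, 113.7 ± 25.17 and 26.42 ± 5.496 CPM in the same order. The lowest library without the Dis3 shRNA held 2.17 times the Dis3 level of the highest library with it, and for Exosc10 this ratio was 2.60. Exosc10 fell by 1.89 on the log2 scale in shExosc10 against shLuc (SE 0.21, adjusted p = 0.00502). Dis3 was lower by a log2 fold change of -1.78 in shDis3 against shLuc (SE 0.24), with an adjusted p of 0.0581 that missed the threshold. The other target in each case was not called (Exosc10 in shDis3 0.21, SE 0.20, and Dis3 in shExosc10 0.12, SE 0.24). Dis3 in shDis3 passed the threshold without shLuc replicate 4, shDis3 replicate 4 or shExosc10 replicate 1 (adjusted p = 0.020, 0.036 and 0.033), and Exosc10 missed it without shExosc10 replicate 2 or 3 (adjusted p = 0.063 and 0.054) and with limma on log2(TPM + 1).

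**Figure D1:**
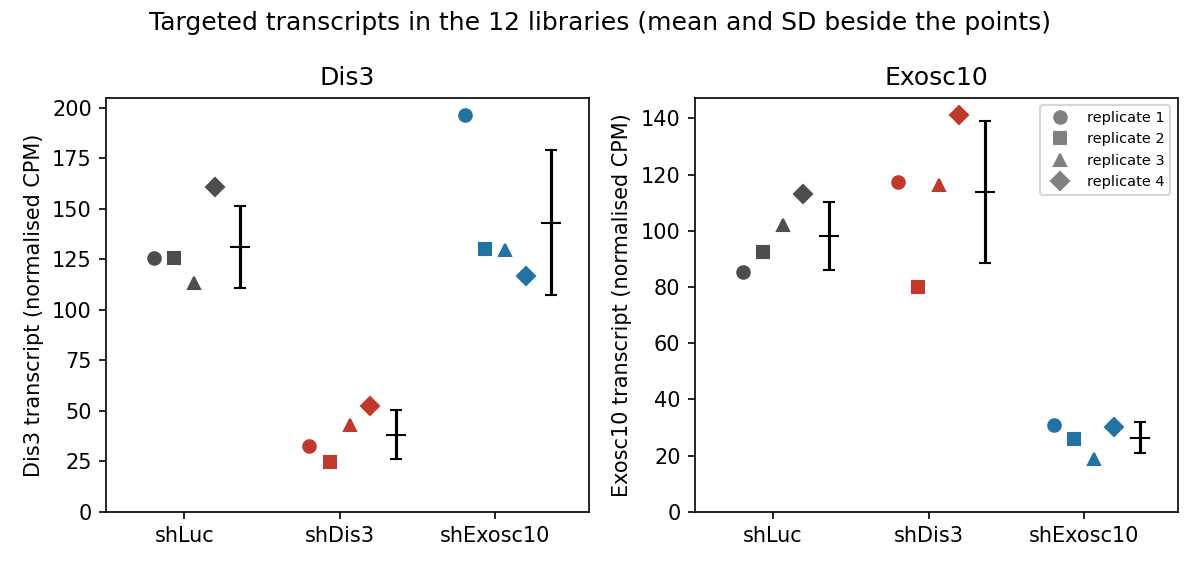
Normalised CPM of Dis3 (left) and Exosc10 (right) in each library, by shRNA group, with symbols for replicates and the group mean and SD (n = 4) beside the points. All 4 shDis3 libraries lay at or below 52.37 CPM of Dis3 and all 4 shExosc10 libraries at or below 30.76 CPM of Exosc10, under every library of the other groups.

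Several libraries resembled a library of another group more than their own. The log2 CPM of shLuc replicate 4 correlated with shDis3 replicate 3 at r = 0.990 across genes, and at most 0.914 with other shLuc libraries. Those of shDis3 replicate 4 and shExosc10 replicate 1 correlated at 0.985, against at most 0.936 and 0.930 within their own groups. Component 1 held 37.3% and component 2 held 32.5% of the variance. Megakaryocyte markers scored 0.89 in shLuc replicate 4 and -1.35 to -0.58 in the other shLuc libraries, and the stem and early progenitor genes scored 1.07 there and -0.65 to -0.44 in the others. Olfactory receptor genes, which liver cells are not known to use and which can register genomic DNA, summed to 7.0 to 621.6 CPM. The sums of the libraries just named were 8.7 (shLuc replicate 4), 7.0 (shDis3 replicate 3), 13.8 (shDis3 replicate 4) and 10.7 CPM (shExosc10 replicate 1). Mitochondrial genes took 9.79% to 20.93% of counts.

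**Figure D2:**
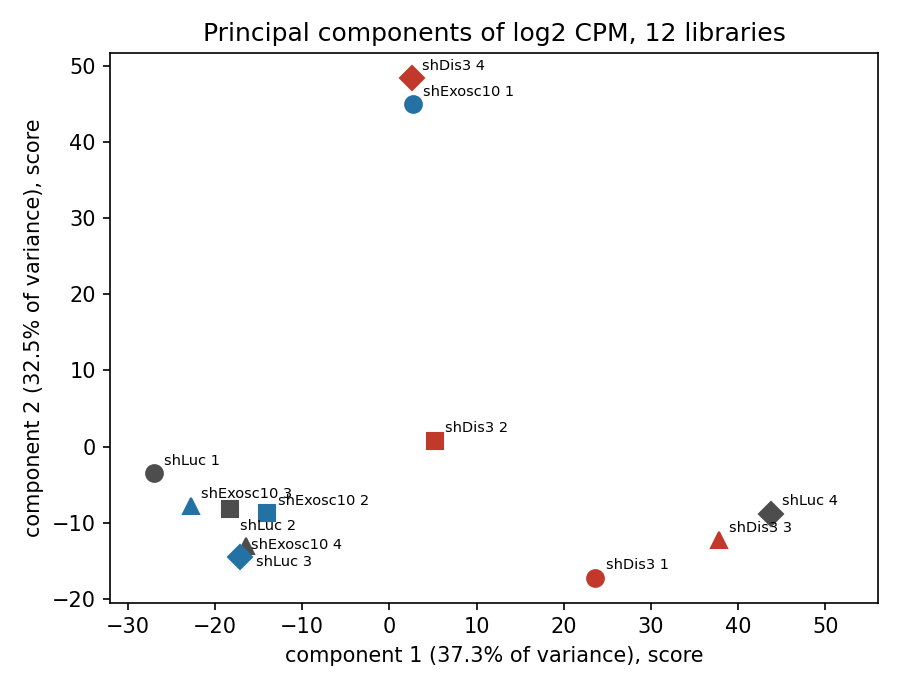
Scores of the 12 libraries on the first principal components of log2 CPM, with the share of variance on each axis, coloured by shRNA group and with symbols for replicates. The points of shLuc 4 and shDis3 3, and those of shDis3 4 and shExosc10 1, lie beside each other and away from most of their groups.

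In shDis3 against shLuc, genes of glycolysis and the hypoxia response, cholesterol synthesis and ATF4 stress signalling lay lower, and megakaryocyte markers, p53 targets and globins lay higher. Of 22 measured glycolysis and hypoxia genes, 21 had a negative log2 fold change, with a median of -0.63 (adjusted p = 2.27e-18 by camera, and adjusted p = 0.272 with an estimated correlation). Gapdh measured 1722 ± 313.5 CPM in shDis3 and 2091 ± 438.1 in shLuc (log2 fold change -0.28, SE 0.19), and Eno1 820.8 ± 207.8 and 1194 ± 275.4 (-0.54, SE 0.22). Among 40 p53 targets 34 were positive, with a median of 0.63 (adjusted p = 2.21e-13, and adjusted p = 0.284 with an estimated correlation). Mdm2, the ubiquitin ligase that restrains p53, measured 134.5 ± 42.04 CPM in shDis3 and 87.81 ± 13.33 in shLuc (0.61, SE 0.23), and Ccng1 386.7 ± 29.29 and 387.3 ± 157.4 (0.00, SE 0.29).

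All 24 cholesterol synthesis genes were negative, with a median of -0.37 (adjusted p = 9.19e-13, and adjusted p = 0.284 with an estimated correlation). Idi1 measured 298.3 ± 106.4 CPM against 388.7 ± 95.22 in shLuc (-0.38, SE 0.24), and Fdps 250.1 ± 86.98 against 338.4 ± 63.3 (-0.44, SE 0.23). Of 30 integrated stress and ATF4 targets 24 were negative, with a median of -0.42 (adjusted p = 2.73e-11, and adjusted p = 0.272 with an estimated correlation). Gars, the glycyl-tRNA synthetase, had a log2 fold change of -0.27 (SE 0.18) and Shmt2, an enzyme of mitochondrial serine metabolism, of -0.40 (SE 0.20). The 6 globins were positive, with a median of 0.82 (adjusted p = 0.000651, and adjusted p = 0.284 with an estimated correlation), although Hba-a1 (0.22, SE 0.45) and Hbb-bs (0.25, SE 0.54) varied by more than their difference, and their reads are shared with near-identical copies. Red cell membrane and maturation genes had a median of -0.33 with 29 of 35 negative (adjusted p = 0.0237, and adjusted p = 0.749 with an estimated correlation). Cd24a had a log2 fold change of -0.34 (SE 0.27) and Sptb, the erythroid beta spectrin, of -0.47 (SE 0.39). The red cell list was not called without shLuc replicate 1, 2 or 3 or shDis3 replicate 2, 3 or 4 (adjusted p = 0.059, 0.28, 0.34, 0.051, 0.16 and 0.34). With the cluster of libraries as a factor it was called higher instead, with 30 of 35 positive and a median of 0.27 (adjusted p = 3.33e-09, and adjusted p = 0.543 with an estimated correlation). In that fit the medians of cholesterol synthesis genes (-0.11, adjusted p = 0.00156) and ATF4 targets (-0.13, adjusted p = 0.0189) lay nearer to 0, and globins had a median of 1.02 (adjusted p = 1.08e-07). These 3 gave adjusted p = 0.749, adjusted p = 0.841 and adjusted p = 0.222 with an estimated correlation. For shDis3 replicate 4, which has no shLuc library in its cluster, that fit reaches shLuc through shExosc10 libraries. Globin scores differed by 1.10 in shDis3 replicate 3 over shLuc replicate 4 and by -0.01 in shDis3 replicate 4 over shExosc10 replicate 1. In the largest cluster they differed by 0.98 in shExosc10 over shLuc. For red cell genes these differences were 0.39, 0.01 and 0.38. The medians of both lists in that fit therefore rest in part on shExosc10 libraries.

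Markers of other blood lineages also lay higher in shDis3 than in shLuc in the 12 libraries, but were not called higher with the cluster of libraries as a factor. Of 21 megakaryocyte markers 19 were positive, with a median of 0.87 (adjusted p = 1.02e-15, and adjusted p = 0.272 with an estimated correlation). Itgb3, a platelet integrin subunit, measured 112.4 ± 21.99 CPM in shDis3 and 53.97 ± 66.75 in shLuc (1.06, SE 0.62), and Nrgn 88.91 ± 37.01 and 101.7 ± 18.02 (-0.19, SE 0.31). With each library left out Itgb3 ran from 0.77 to 2.45. Granulocyte markers had a median of 0.73 (adjusted p = 0.000107, and adjusted p = 0.384 with an estimated correlation). Mpo, the neutrophil myeloperoxidase, measured 2655 ± 903.2 against 1499 ± 1432 CPM (0.82, SE 0.48), and Elane 227.2 ± 130.8 against 133.8 ± 53.26 (0.76, SE 0.37). The log2 fold change of Mpo was 0.56 to 1.75 with each library left out. Stem and early progenitor genes had a median of 0.39 (adjusted p = 0.000194, and adjusted p = 0.624 with an estimated correlation), with Myb at 0.36 (SE 0.32) and the stem cell factor receptor Kit at -0.63 (SE 0.21). In the fit with that factor, stem and early progenitor genes were called lower (median -0.21, adjusted p = 0.00156, and adjusted p = 0.546 with an estimated correlation), as were granulocyte markers (median -0.16, adjusted p = 0.00352, and adjusted p = 0.732 with an estimated correlation).

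Other lists were also called with the preset correlation in this comparison. Macrophage and monocyte markers had a median of 0.68 (adjusted p = 2.9e-05), endothelial and stromal markers of 0.40 (adjusted p = 0.0266) and ribosome biogenesis genes of 0.11 (adjusted p = 0.0368). With an estimated correlation these gave adjusted p = 0.384, adjusted p = 0.384 and adjusted p = 0.781. Ribosomal protein genes had a median of -0.16 (adjusted p = 0.00144), other structured small RNAs of -1.11 (adjusted p = 0.00203), heme synthesis and iron uptake genes of -0.26 (adjusted p = 0.0158), and snoRNAs and scaRNAs of -1.09 (adjusted p = 0.0266). Each of these 4 lists gave adjusted p = 0.749 with an estimated correlation. Of 35 splits of the 8 libraries into 4 and 4, 24 gave a camera p as small for ribosomal protein genes and 23 for ribosome biogenesis. For snoRNAs and scaRNAs 19 did, structured small RNAs 17, heme genes 15, endothelial markers 9 and macrophage markers 3. Among lists described above, red cell genes had 18, stem genes 14, granulocyte markers 8, globins 6 and cholesterol synthesis 2. Chance is therefore not excluded for these lists. The call was lost for ribosomal protein genes and structured small RNAs without shLuc replicate 1 or 3 or shDis3 replicate 3 (adjusted p = 0.56, 0.50 and 0.95, and 0.43, 0.089 and 0.24), and for snoRNAs and scaRNAs without these or shDis3 replicate 1 (adjusted p = 0.89, 0.28, 0.60 and 0.053). It was lost for heme genes without shLuc replicate 2 or 3 or shDis3 replicate 2 or 3 (adjusted p = 0.15, 0.34, 0.14 and 0.15), and for endothelial markers without shLuc replicate 2 or shDis3 replicate 3 (adjusted p = 0.089 and 0.056). The endothelial list turned to a mean of -0.02 without shDis3 replicate 2 (adjusted p = 0.044). Ribosome biogenesis was not called without shLuc replicate 1, 2 or 3 or shDis3 replicate 3 (adjusted p = 0.058, 0.16, 0.20 and 0.52), and had a mean of -0.03 without shDis3 replicate 4 (adjusted p = 0.38). Under the cluster factor heme genes were called higher (median 0.13, adjusted p = 0.00352, and adjusted p = 0.749 with an estimated correlation). Macrophage markers (median -0.21, adjusted p = 0.0548), endothelial markers (0.10, adjusted p = 0.84), ribosome biogenesis genes (-0.03, adjusted p = 0.466), structured small RNAs (-0.22, adjusted p = 0.241) and snoRNAs and scaRNAs (-0.30, adjusted p = 0.534) were not called there. Ribosomal protein genes were called lower there too (median -0.11, adjusted p = 2.47e-06, and adjusted p = 0.749 with an estimated correlation). The 20 remaining lists were exosome subunits, exosome adaptors and cofactors, snoRNA host genes, clustered histone genes, apoptosis regulators, DNA damage repair and checkpoint, erythroid transcription factors, mast cell and basophil, lymphoid and hepatocyte markers, interferon-stimulated genes, immediate early and heat shock genes, NF-kB and inflammatory genes, S phase genes, G2 and M phase genes, autophagy and mitochondrial clearance, erythropoietin and STAT5 response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs and sex-linked marker genes. They had adjusted p from 0.0525 to 0.939. Of these, the cluster factor gave calls for mast cell and basophil (median -0.54, adjusted p = 3.45e-07) and lymphoid markers (-0.28, adjusted p = 0.0282), immediate early genes (-0.14, adjusted p = 0.0108) and histone genes (0.08, adjusted p = 0.0259). Those 4 gave adjusted p = 0.222, adjusted p = 0.732, adjusted p = 0.720 and adjusted p = 0.975 with an estimated correlation.

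No single gene passed the edgeR threshold in shDis3 against shLuc (0 higher, 0 lower). At an unadjusted p under 0.05 there were 719 genes, 354 higher and 365 lower, where 883 would be called by chance. DESeq2 called 10 genes higher and 18 lower, and limma on log2(TPM + 1) called 0. Adjusted over the list alone, 16 glycolysis and hypoxia genes and 5 ATF4 targets were lower, 1 megakaryocyte marker and 1 p53 target were higher, 1 gene of the autophagy list was lower, and no member of the other lists passed. The counts were 772 without shLuc replicate 4, shDis3 replicate 4 and shExosc10 replicate 1 (545 higher, 227 lower), 146 without shLuc replicate 4 alone, and 123 with no filter on low counts. With the cluster of libraries as a factor, glycolysis and hypoxia genes had a median of -0.09 (adjusted p = 0.241), megakaryocyte markers of 0.12 (adjusted p = 0.84) and p53 targets of 0.78 (adjusted p = 1.46e-43, and adjusted p = 0.0879 with an estimated correlation). Over the list alone in that fit, 15 p53 targets were higher, and no ATF4 target or megakaryocyte marker passed. Without the 3 libraries, megakaryocyte markers had a median of 1.82 (adjusted p = 2.59e-21, and adjusted p = 0.0479 with an estimated correlation). That fit left out shLuc replicate 4, chosen by its expression, which scored 0.89 for this list (other shLuc libraries -1.35 to -0.58). The shLuc and shDis3 libraries left share no cluster, so effects of the shRNA and of the clusters cannot be told apart there.

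**Figure D3:**
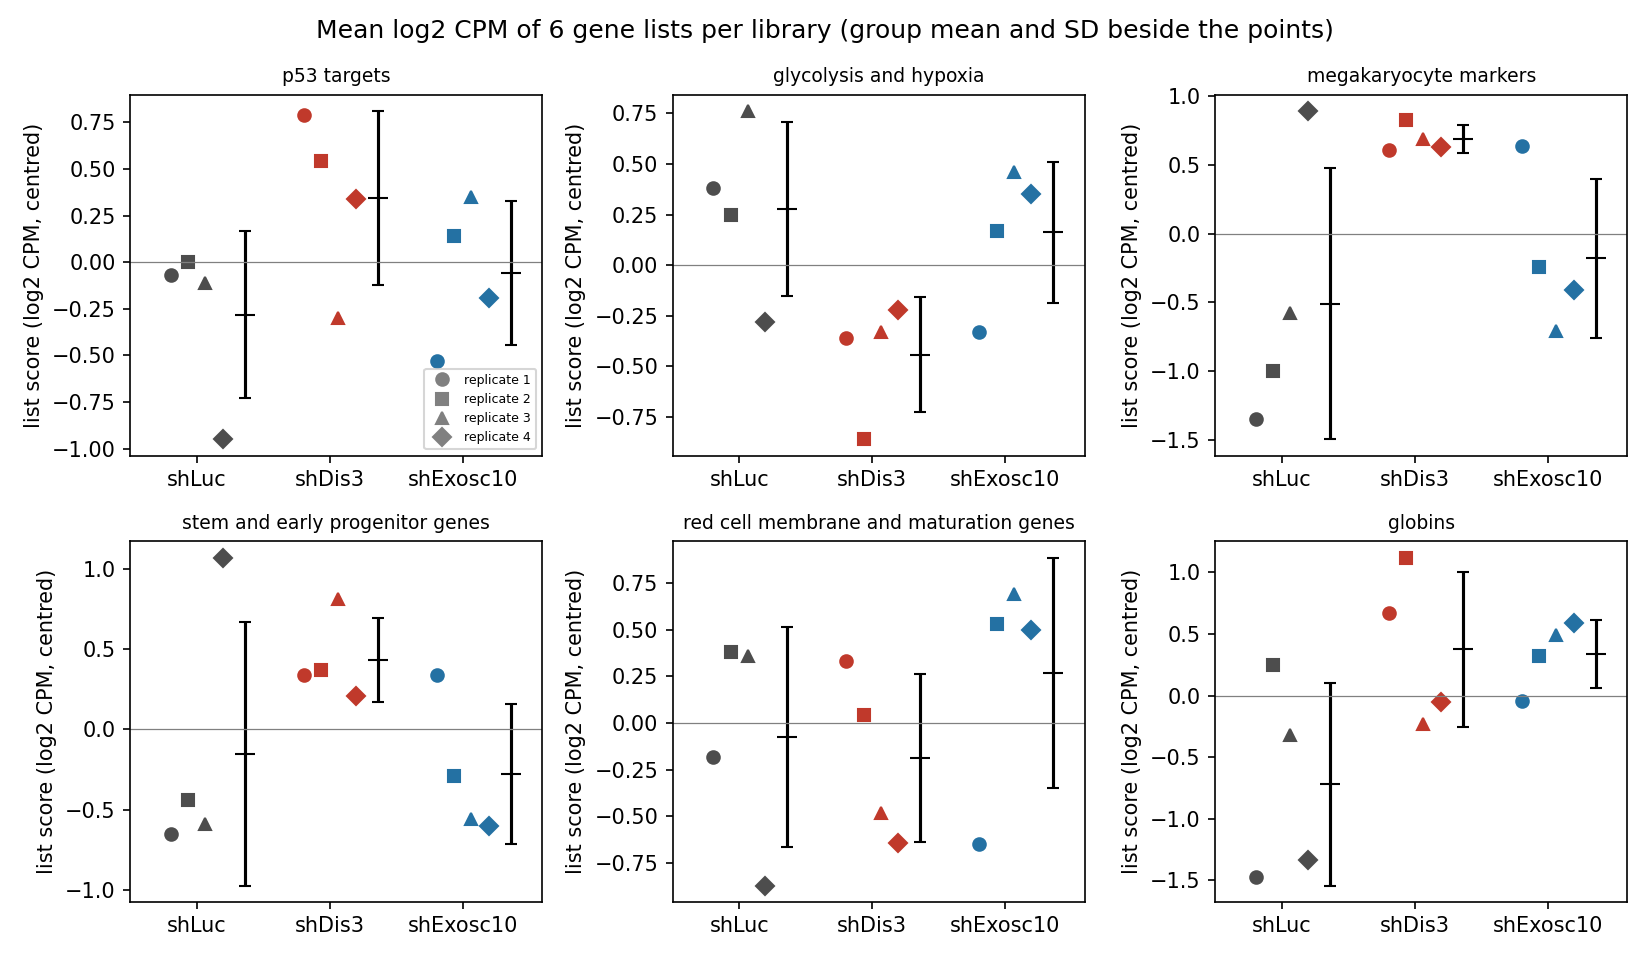
Scores of 6 gene lists in each library (mean log2 CPM of the members, centred over the 12 libraries), by shRNA group, with symbols for replicates and the group mean and SD (n = 4) beside the points. For p53 targets the shLuc libraries spanned -0.95 to 0.00 and the shDis3 libraries -0.30 to 0.79, and for megakaryocyte markers shLuc replicate 4 lay at 0.89, among the shDis3 libraries.

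Structured non-coding RNA lay lower in shDis3 than in shLuc in the 12 libraries. Of 27 annotated snoRNAs that were measured, 26 were negative, with a median log2 fold change of -1.11 (adjusted p = 8.74e-05, and adjusted p = 0.561 with an estimated correlation). All 11 snRNAs were negative, with a median of -1.32 (adjusted p = 0.00284, and adjusted p = 0.456 with an estimated correlation). The snoRNA class scored 2.16 and 1.61 in shLuc replicates 1 and 3 and -0.58 and -1.58 in replicates 2 and 4. Both calls were lost without shLuc replicate 1, shLuc replicate 3 or shDis3 replicate 3 (adjusted p = 0.30, 0.059 and 0.39 for snoRNAs, and 0.11, 0.14 and 0.28 for snRNAs), and with the cluster of libraries as a factor (median -0.23, adjusted p = 0.0729, and median -0.11, adjusted p = 0.204). Protein-coding genes (adjusted p = 0.0528), long non-coding and antisense RNAs (0.462) and processed pseudogenes (0.247) were not called. The cluster factor gave calls for long non-coding RNA (median 0.23, adjusted p = 0.00700) and pseudogenes (-0.10, adjusted p = 0.0212), each with an adjusted p = 0.673 with an estimated correlation. Genomic DNA as a source of these 2 calls was not tested.

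In shExosc10 against shLuc, Exosc10 was the only gene of 17651 called (0 higher, 1 lower), and 371 genes had an unadjusted p under 0.05. The 6 globins had positive log2 fold changes with a median of 0.97 (adjusted p = 0.000456, and adjusted p = 0.874 with an estimated correlation). Hba-a1 measured 458.0 ± 116.5 CPM in shExosc10 and 307.1 ± 218.8 in shLuc (0.58, SE 0.45), and Hbb-bs 337.9 ± 144.5 and 198.4 ± 150.1 (0.77, SE 0.55). Of 35 red cell membrane and maturation genes 26 were positive, with a median of 0.19 (adjusted p = 0.0157, and adjusted p = 0.995 with an estimated correlation). Cd24a had a log2 fold change of 0.39 (SE 0.27) and Sptb of -0.04 (SE 0.39). The call of that list was lost without shLuc replicate 4 or shExosc10 replicate 2, 3 or 4 (adjusted p = 0.99, 0.062, 0.30 and 0.066). Both lists were called higher with the cluster of libraries as a factor (globins 0.92, adjusted p = 7.01e-07, and red cell genes 0.21, adjusted p = 5.25e-08, each with an adjusted p = 0.750 with an estimated correlation).

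Erythroid transcription factors lay slightly lower in shExosc10, with 16 of 18 negative and a median of -0.19 (adjusted p = 0.00675, and adjusted p = 0.995 with an estimated correlation). Zfpm1, the GATA1 cofactor FOG1, measured 228.3 ± 73.48 CPM against 290.1 ± 91.59 (-0.35, SE 0.38), and E2f4 194.9 ± 59.72 against 311.1 ± 32.86 (-0.67, SE 0.27). That list scored -0.69 in shExosc10 replicate 1 and 0.07 to 0.20 in the other shExosc10 libraries, and without that replicate its adjusted p was 0.26. Of 15 genes of the erythropoietin and STAT5 response 13 were negative, with a median of -0.22 (adjusted p = 0.0212, and adjusted p = 0.995 with an estimated correlation). Stat5b measured 84.91 ± 7.066 against 109.3 ± 10.52 CPM (-0.36, SE 0.17), and the kinase Jak2 69.27 ± 5.032 against 69.18 ± 15.64 (0.00, SE 0.18). The call was lost without shLuc replicate 2 or shExosc10 replicate 1 (adjusted p = 0.075 and 0.35). The clustered histone genes were called higher by the test and had a mean of 0.14 but a median of 0.01 (adjusted p = 0.0212, and adjusted p = 0.995 with an estimated correlation), with Hist2h2aa1 at -0.01 (SE 0.31) and Hist1h1c at 0.07 (SE 0.26). That list was not called without shLuc replicate 2 or 4 or shExosc10 replicate 1 or 2 (adjusted p = 0.90, 0.099, 0.54 and 0.060). It was called lower with the cluster of libraries as a factor (median -0.22, adjusted p = 0.00031, and adjusted p = 0.933 with an estimated correlation), where erythroid transcription factors (median 0.04, adjusted p = 0.918) and the erythropoietin and STAT5 response (-0.07, adjusted p = 0.115) were not called.

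Smaller shifts were called for immediate early and heat shock genes (median -0.18) and integrated stress and ATF4 targets (-0.16), each with an adjusted p = 0.0212, and for stem and early progenitor genes (-0.25) and glycolysis and hypoxia genes (-0.18), each with an adjusted p = 0.0333. All 4 gave an adjusted p = 0.995 with an estimated correlation. The immediate early list was not called without shLuc replicate 1 or 4 or shExosc10 replicate 4 (adjusted p = 0.059, 0.18 and 0.081), and the ATF4 list not without shLuc replicate 1 or 3 or shExosc10 replicate 1 (adjusted p = 0.14, 0.064 and 0.19). The stem list was not called without shExosc10 replicate 3 or 4 (adjusted p = 0.27 and 0.26) and turned to a mean of 0.45 without shLuc replicate 4 (adjusted p = 0.032). The glycolysis list was not called without shLuc replicate 1 or shExosc10 replicate 1 or 2 (adjusted p = 0.17, 0.50 and 0.062) and had a mean of 0.02 without shLuc replicate 3 (adjusted p = 0.87). Under the cluster factor the immediate early (median -0.13, adjusted p = 0.158) and stem lists (0.01, adjusted p = 0.849) were not called. The calls of ATF4 targets (median -0.19, adjusted p = 0.000171, and adjusted p = 0.750 with an estimated correlation) and glycolysis genes (-0.18, adjusted p = 0.000179, and adjusted p = 0.820 with an estimated correlation) were kept. The 27 remaining lists, among them p53 targets, cholesterol synthesis, heme synthesis, ribosomal protein genes, hepatocyte and lymphoid markers, NF-kB genes and mitochondrially encoded mRNAs, had adjusted p from 0.0657 to 0.996. Of these, the cluster factor gave lower calls for ribosomal protein genes (median -0.21, 0 of 76 positive, adjusted p = 2.36e-19), oxidative phosphorylation (-0.16, adjusted p = 7.99e-08), structured small RNAs (-0.77, adjusted p = 4.09e-06), snoRNAs and scaRNAs (-0.76, adjusted p = 0.00197) and S phase genes (-0.11, adjusted p = 0.0241). The first 4 gave adjusted p = 0.750 with an estimated correlation, and S phase genes adjusted p = 0.923. Of 35 splits of the 8 libraries into 4 and 4 in that fit, 18 gave a camera p as small for snoRNAs and scaRNAs. For structured small RNAs 15 did, for oxidative phosphorylation 9, for ribosomal protein genes 6 and for S phase genes 3. Chance is therefore not excluded for these lists. Megakaryocyte markers were called higher there (median 0.27, adjusted p = 0.0393, and adjusted p = 0.820 with an estimated correlation). Among RNA classes, long non-coding and antisense RNA was called higher (median 0.17, adjusted p = 0.0228, and adjusted p = 0.784 with an estimated correlation). Protein-coding genes were called lower with a median of 0.00 and a mean of 0.02, so that test and mean differed in sign (adjusted p = 0.039, and adjusted p = 0.106 with an estimated correlation). Both class calls were lost without shLuc replicate 1 or 4, shDis3 replicate 4 or shExosc10 replicate 2, 3 or 4 (adjusted p = 0.092, 0.13, 0.11, 0.088, 0.26 and 0.69 for long non-coding RNA, and 0.092, 0.098, 0.11, 0.088, 0.26 and 0.82 for protein-coding genes), and the protein-coding call also without shDis3 replicate 2 (adjusted p = 0.058). The mean of long non-coding RNA was -0.07 without shLuc replicate 4 or shExosc10 replicate 4. Scores of that class were highest in shDis3 replicate 2 (1.25), shExosc10 replicate 4 (0.78) and shLuc replicate 2 (0.75). These libraries also had the highest olfactory receptor sums (621.6, 260.4 and 340.7 CPM). Scores were -0.96 to -0.73 in shLuc replicate 4, shExosc10 replicate 1 and shDis3 replicates 3 and 4, with sums of 7.0 to 13.8 CPM. The class thus moved with the genomic DNA signal, and DNA as a source of its call was not tested. Processed pseudogenes, snoRNAs and snRNAs had adjusted p of 0.143, 0.520 and 0.117. Structured RNA was called lower in shExosc10 than in shLuc under the cluster factor, with medians of -0.84 for snoRNAs (0 of 27 positive, adjusted p = 3.51e-08) and -1.06 for snRNAs (0 of 11, adjusted p = 1.14e-06), each with an adjusted p = 0.336 with an estimated correlation. Without 3 libraries the snoRNA median was -0.88 (adjusted p = 9.53e-10, and adjusted p = 0.461 with an estimated correlation). That of snRNAs was -1.17 (adjusted p = 4.66e-08, and adjusted p = 0.226 with an estimated correlation). This fit compares only shLuc and shExosc10 libraries of the largest cluster and is no separate test. There snoRNAs scored 2.16, -0.58 and 1.61 in shLuc replicates 1 to 3. They scored -0.19, 0.02 and 1.05 in shExosc10 replicates 2 to 4, each above shLuc replicate 2. For snRNAs, shLuc replicate 2 (0.36) lay below shExosc10 replicate 2 (1.24) only.

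Adjusted over the list alone, 1 megakaryocyte marker was higher in shExosc10 than in shLuc and no member of the other lists passed. DESeq2 called 3 genes higher and 3 lower, limma on log2(TPM + 1) called 0, and with no filter on low counts 5 were higher and 5 lower. The count was 0 without shExosc10 replicate 2 or 3, 2 without shLuc replicate 4, and 7 with the cluster of libraries as a factor (6 higher, 1 lower).

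The direct comparison of shDis3 with shExosc10 asked where the knockdowns differed. Exosc10 rose by 2.11 on the log2 scale (SE 0.21, adjusted p = 0.00144) and Dis3 fell by 1.90 (SE 0.24, adjusted p = 0.0138), and no other gene passed. Dis3 missed the threshold without shDis3 replicate 1 or 3 or shExosc10 replicate 3 (adjusted p = 0.18, 0.071 and 0.053), with the replicate block (0.059), with the 8 libraries alone (0.080), tested against a log2 fold change of 0.5 (0.064) and with limma, where Exosc10 missed it too. Cholesterol synthesis genes lay lower in shDis3, with 22 of 24 negative and a median of -0.47 (adjusted p = 2.06e-12, and adjusted p = 0.485 with an estimated correlation). Idi1 measured 298.3 ± 106.4 CPM in shDis3 and 454.0 ± 56.14 in shExosc10 (-0.61, SE 0.24), and Fdps 250.1 ± 86.98 and 346.4 ± 51.63 (-0.47). Of 22 glycolysis and hypoxia genes 21 were negative, with a median of -0.46 (adjusted p = 7.03e-09, and adjusted p = 0.485 with an estimated correlation), with Gapdh at -0.10 and Eno1 at -0.30. Of 35 red cell membrane and maturation genes 30 were negative, with a median of -0.45 (adjusted p = 1.54e-05, and adjusted p = 0.706 with an estimated correlation), with Cd24a at -0.72 and Sptb at -0.43. The glycolysis and red cell lists were not called with the cluster of libraries as a factor (medians 0.16 and 0.07, adjusted p = 0.132 and 0.58), and the cholesterol median was -0.19 (adjusted p = 0.000207, and adjusted p = 0.979 with an estimated correlation).

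Lists that lay higher in shDis3 than in shExosc10 in the 12 libraries were markers of other lineages and p53 targets. Megakaryocyte markers had a median of 0.86 with 20 of 21 positive (adjusted p = 4.17e-09), stem and early progenitor genes of 0.65 with 22 of 24 (adjusted p = 1.8e-07), macrophage and monocyte markers of 0.81 with 13 of 15 (adjusted p = 5.14e-07), granulocyte markers of 0.71 with 17 of 19 (adjusted p = 5.73e-05) and endothelial and stromal markers of 0.47 with 12 of 13 (adjusted p = 0.00851). Each of these 5 lists gave adjusted p = 0.485 with an estimated correlation. Itgb3 measured 112.4 ± 21.99 against 52.71 ± 33.97 CPM (1.09, SE 0.62) and Nrgn had a log2 fold change of 0.28. Kit stood at -0.46 and Myb at 0.24. The macrophage lysozyme Lyz2 stood at 0.09, and Spi1, the myeloid transcription factor PU.1, measured 52.57 ± 8.579 against 34.85 ± 7.494 CPM (0.59, SE 0.23). Of 40 p53 targets 31 were positive, with a median of 0.51 (adjusted p = 3.48e-06, and adjusted p = 0.550 with an estimated correlation), with Mdm2 at 0.41 and Ccng1 at -0.22. Under the cluster factor p53 targets had a median of 0.66 (adjusted p = 1.56e-33, and adjusted p = 0.146 with an estimated correlation). However, 3 of the lineage lists were called lower: stem and early progenitor genes (median -0.21, adjusted p = 0.00323), granulocyte markers (-0.23, adjusted p = 0.000404) and megakaryocyte markers (-0.24, adjusted p = 0.0218). These 3 gave adjusted p = 0.742, adjusted p = 0.824 and adjusted p = 0.979 with an estimated correlation. Macrophage (-0.04, adjusted p = 0.876) and endothelial markers (-0.01, adjusted p = 0.926) were not called.

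Further lists lower in shDis3 than in shExosc10 were ATF4 targets (median -0.27, adjusted p = 0.000263), histone genes (-0.18, adjusted p = 0.000412), ribosomal protein genes (-0.16, adjusted p = 0.00208), nuclear-encoded oxidative phosphorylation (-0.16, adjusted p = 0.00851) and heme synthesis (-0.20, adjusted p = 0.0133). With an estimated correlation they gave adjusted p = 0.506, adjusted p = 0.845, adjusted p = 0.847, adjusted p = 0.847 and adjusted p = 0.797. The calls were lost without shDis3 replicate 2 for ATF4 targets (adjusted p = 0.054), without shDis3 replicate 3 for histone genes, ribosomal protein genes, oxidative phosphorylation, heme synthesis and endothelial markers (adjusted p = 0.49, 0.82, 0.93, 0.075 and 0.060), and without shExosc10 replicate 1 for the first 3 of these (adjusted p = 0.26, 0.95 and 0.97). Histone genes and oxidative phosphorylation also lost it without shDis3 replicate 1 (adjusted p = 0.085 and 0.051), and heme synthesis without shDis3 replicate 2 or shExosc10 replicate 3 (adjusted p = 0.11 and 0.081). With the cluster of libraries as a factor 4 of these lists were called higher: histone genes (median 0.27, adjusted p = 3.82e-07), heme synthesis (0.13, adjusted p = 0.000823), ribosomal protein genes (0.08, adjusted p = 0.00323) and oxidative phosphorylation (0.08, adjusted p = 0.0102). Each gave adjusted p = 0.979 with an estimated correlation, and ATF4 targets were not called (median 0.01, adjusted p = 0.608). The 22 remaining lists, globins among them, had adjusted p from 0.0738 to 0.926. Of these, the cluster factor gave calls for mast cell and basophil markers (median -0.54, adjusted p = 0.000602), the erythropoietin and STAT5 response (0.23, adjusted p = 0.0102) and structured small RNAs (0.59, adjusted p = 0.0260), with adjusted p = 0.742, adjusted p = 0.742 and adjusted p = 0.979 with an estimated correlation. Among RNA classes, protein-coding genes were called higher (median 0.05, adjusted p = 0.000734, and adjusted p = 0.00468 with an estimated correlation), with a mean of -0.47 without shDis3 replicate 2 and of -0.01 without shExosc10 replicate 1. However, fry pointed lower (adjusted p = 0.866) and the class score differed by -0.04 (exact permutation p = 0.77). As camera compares a class with the other genes, its call is by itself no rise. Scores of protein-coding genes (0.33) and pseudogenes (0.56) were highest in shDis3 replicate 2, which had the highest olfactory receptor sum. Genomic DNA as a source of the class calls was not tested. Lower calls were made for snoRNAs (median -0.52, adjusted p = 0.00288), long non-coding and antisense RNA (-0.08, adjusted p = 0.00664) and processed pseudogenes (-0.16, adjusted p = 0.0218), each with an adjusted p = 0.623 with an estimated correlation, and snRNAs were not called (adjusted p = 0.298). Without shDis3 replicate 3 these lower calls were lost (adjusted p = 0.46, 0.38 and 0.38). Under the cluster factor the call of protein-coding genes was lost (median 0.01, adjusted p = 0.772), as were those of long non-coding RNA (0.11, adjusted p = 0.285) and pseudogenes (-0.06, adjusted p = 0.2). There snoRNAs (median 0.55, adjusted p = 0.0373, and adjusted p = 0.847 with an estimated correlation) and snRNAs (0.58, adjusted p = 0.00177, and adjusted p = 0.810 with an estimated correlation) were called higher. Long non-coding RNA was also not called without shDis3 replicate 4 or shExosc10 replicate 4 (adjusted p = 0.26 and 0.16) and had a mean of 0.03 without shDis3 replicate 1 (adjusted p = 0.011). Pseudogenes lost the call without shDis3 replicate 1 or 4 or shExosc10 replicate 1 (adjusted p = 0.092, 0.056 and 0.23), and protein-coding genes without shDis3 replicate 4 (adjusted p = 0.11).

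By edgeR 1 gene was higher and 1 lower in shDis3 against shExosc10, and 1056 genes had an unadjusted p under 0.05. Adjusted over the list alone, 10 cholesterol synthesis genes, 5 glycolysis and hypoxia genes and 2 genes of the autophagy list were lower, and no member of the other lists passed. DESeq2 called 10 higher and 39 lower, limma on log2(TPM + 1) called 0, and the count was 617 without the 3 libraries far from their groups (387 higher, 230 lower) and 179 with no filter on low counts. It was 1 without shDis3 replicate 1 or 3 or shExosc10 replicate 3. The smallest p of the exact permutation tests on list scores was 0.029, 0.057 and 0.029 in the 3 comparisons in the order given, and no list passed after adjustment (smallest adjusted p = 0.64, 0.91 and 0.34).

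No gene other than Exosc10 was called in either knockdown against shLuc, and 0 genes were shared between their calls. Across 17651 genes, which are not independent replicates, the log2 fold changes of the knockdowns correlated at r = 0.396 with a covariance of 0.106. Unchanged groups simulated with 4 shared control libraries gave r = 0.501 (0.479 to 0.520) and a covariance of 0.482, above the observed values. The simulated libraries were independent, whereas real libraries of different groups clustered together. The draws therefore do not show what shared controls alone would give here. With the controls split 2 and 2, r ranged from -0.391 to 0.0487.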

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

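All tests of an explanation in this part were chosen after the result was seen. Of 261 groups of 4 libraries examined (library measures, list scores and 40 named genes), 26 held a library whose gap to the nearest other, relative to the range of the group, was above Dixon's critical value for 4 samples. In independent groups chance gives this in about 1 in 20, so in about 13. The groups here are not independent, and some named genes were chosen in fits that left out or modelled the libraries that stood apart. The 26 against 13 is therefore no test.

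In shLuc, replicate 4 stood apart. Its list scores were -0.95 for p53 targets (others -0.11 to 0.00), 1.07 for stem and early progenitor genes (others -0.65 to -0.44), -0.20 for ATF4 targets (others 0.37 to 0.45), 0.25 for ribosome biogenesis and -0.02 for G2 and M phase genes. It held 154 CPM of Itgb3 (others 17.58 to 25.27), 3631 CPM of Mpo (others 582.8 to 1010), 64.5 CPM of Cd34 (others 6.23 to 8.62), 68.05 CPM of Mdm2 (others 92.6 to 97.3), 59.81 CPM of Rab1a (others 17.84 to 18.64) and 449.7 CPM of Serinc3 (others 234.1 to 250.3).

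In shExosc10, replicate 1 stood apart. Its list scores were -0.69 for erythroid transcription factors (others 0.07 to 0.20), -0.65 for red cell membrane and maturation genes (others 0.50 to 0.69), -0.80 for the erythropoietin and STAT5 response (others 0.07 to 0.11), 1.17 for mast cell and basophil markers (others -0.82 to -0.61), 0.11 for DNA damage repair and 0.19 for S phase genes. It held 257.4 CPM of Sptb (others 917.2 to 985.7), 59.52 CPM of Cd34 (others 7.31 to 8.29) and 196.2 CPM of Dis3 (others 116.6 to 130.0). Replicate 4 of shExosc10 held 361.3 CPM of Shmt2 (others 286.5 to 299.0). In shDis3, replicate 2 held 35216 genes with a count (others 18792 to 21478), an olfactory receptor sum of 621.6 CPM (others 7.0 to 30.9) and 197.5 CPM of Shmt2 (others 346.6 to 347.5). Replicate 3 of shDis3 held 8.18 CPM of Eda2r (others 19.4 to 21.62), and replicate 4 held 97.83 CPM of Rab1a (others 65.38 to 69.71).

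Libraries closer to another group than to their own were weighed first. A swap of labels between the groups was excluded, as each target was at least 2.17 times higher in every library without its shRNA than in any with it. Genomic DNA in the other libraries of the group can only add reads, and it was excluded as the whole source for shLuc replicate 4 and shExosc10 replicate 1, since 56.6% and 36.3% of genes at least 2-fold apart were higher there. For shDis3 replicate 4 only 10.2% were higher (88 of 860), so this measure does not exclude DNA there. Its r was 0.909 with shDis3 replicate 3, which had the lowest olfactory receptor sum (7.0 CPM), so DNA did not make that distance. With replicate 2, which had the highest sum (621.6 CPM), r was 0.936. However, shDis3 replicate 3 itself lay beside shLuc replicate 4 (r = 0.990). DNA is therefore not excluded as the source of the distance from shDis3 replicates 1 and 2. A culture, harvest or library batch could place libraries of different groups together (lowest r of such pairs 0.985), but it and a biological difference between cultures cannot be told apart, because the labels give no dates.

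The p53 targets were weighed as a possible response to the Dis3 shRNA. Their median was 0.47 in shDis3 replicate 3 over shLuc replicate 4 (34 of 40 higher). In shDis3 replicate 4 over shExosc10 replicate 1 it was 0.80 (37 of 40). Within these pairs of 1 cluster, the cluster of libraries did not account for them. More cells of other types did not account for them in these pairs, since the highest of 7 marker lists lay below the p53 median by at least 0.39, but a difference in erythroid maturity stays open, as red cell genes and globins were also higher in the first pair (medians 0.32 and 1.06) though near 0 in the second (0.03 and 0.06). Mast cell and basophil markers (-0.52 and -0.34) and stem and early progenitor genes (-0.30 and -0.13) were lower in both pairs. Fewer such cells in shDis3 was not tested. With the cluster as a factor, 1 of 34 splits of the 8 libraries, the real one, gave a set-test p as small (4.06e-45, next 9.93e-15). That fit takes the shDis3 effect against shLuc from the first pair. It also uses the second pair, joined to shExosc10 over shLuc in the largest cluster. Without the factor 3 of 35 splits gave a p as small (1.84e-14, smallest other 8.05e-24). This list was picked from 36 after the data were seen, so chance is not excluded. Without 3 libraries 4 of 10 splits, too few for a share under 0.05, gave a p as small (2.69e-05, smallest other 8.79e-24). An effect of this hairpin on other transcripts is untested, and shDis3 replicates 1 and 2 share a cluster with no other group. Each pair compares single libraries, and the second holds no control, so a fall in shExosc10 would look the same there. The p53 scores of shLuc replicate 4 (-0.95) and shExosc10 replicate 1 (-0.53) were the lowest of their groups. That of shDis3 replicate 3 (-0.30) lay below shLuc replicates 1 to 3 (-0.11 to 0.00). The list also missed the threshold with an estimated correlation (adjusted p = 0.0879 with the cluster factor). For these reasons a p53 response was not established.

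Glycolysis and hypoxia genes and megakaryocyte markers, the lists with the smallest p in shDis3 against shLuc, were weighed against the cluster of libraries. Within the pairs of different groups, the hypoxia median was -0.10 and 0.14, against -0.63 in the 12 libraries. Megakaryocyte markers had medians of -0.13 and 0.05, against 0.87. In both lists the pairs moved in opposite directions. Only the pair of shDis3 replicate 3 and shLuc replicate 4 holds a control, so an effect shared by both knockdowns would not show in the other. In that pair both medians lay nearer to 0 than in the 12 libraries, as a difference between clusters of libraries, technical or biological, would give. Glycolysis and hypoxia genes were still lower there (16 of 22), at percentile 0.3 of 10000 random lists matched on mean expression. In the other pair they stood at percentile 99.3. Megakaryocyte markers were lower in the pair with the control (15 of 21, percentile 3.9), opposite to the 12 libraries. Random lists do not carry the correlation between members. However, the pair with the control compares single libraries and does not decide the question. An effect limited to shDis3 replicates 1 and 2 stays open, as no other group shares their cluster. In the 12 libraries, the real split of 35 had the smallest set-test p for glycolysis genes (6.31e-20, next 4.77e-16). It also did for ATF4 targets (3.79e-12, next 1.94e-07). For megakaryocyte markers 3 gave a p as small. With the cluster factor 23, 12 and 29 of 34 did, in that order. ATF4 scores were -0.41 to -0.38 in shDis3 and -0.20 to 0.45 in shLuc (exact permutation p = 0.029, adjusted p = 0.64). These lists were picked after the data were seen, so chance is not excluded.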

How the results depend on the processing

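The fits without 3 or 4 libraries and with the cluster of libraries as a factor were chosen after the data were seen, and all other alternatives before. Values are given below for counts, targets and named genes, and for lists and RNA classes called in the 12 libraries where the sign turned or, in fits other than those with 1 library left out, the call was lost. Over the 69 uncalled list results, 201 of 1311 values had the opposite sign, 18 of them called (35 of 69 with the cluster as a factor, 127 of 828 with a library left out, 13 and 16 without 3 and 4 libraries, 7 with the replicate block and 3 with RLE factors). A further 174 kept the sign and gained a call (7 with the cluster as a factor, 119 with a library left out, 15 and 21 without 3 and 4 libraries, 8 with the block and 4 with RLE factors). Over the 7 uncalled class results 18 of 133 had the opposite sign, 4 of them called, and 27 kept the sign and gained a call. Unless a cause is named, the cause was not tested. At these depths the spread between libraries, not counting error, set the limit for abundant genes. Of 56 uncalled results of named genes, calls with the same sign were gained for 6 with the cluster as a factor, 3 by DESeq2, 7 without a filter, 12 without 3 libraries and 19 without 4, and in 3 values with a library left out.

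The count for shDis3 against shLuc (0) was 1 under RLE factors, upper-quartile factors, a 5 CPM filter, protein-coding nuclear genes only or a robust spread estimate, the gene being Dis3 each time. It was 2 with the cluster as a factor, 28 by DESeq2, 123 without a filter, 772 without 3 libraries, 724 without 4, and 0 to 146 with each library left out (146 without shLuc replicate 4). For shExosc10 against shLuc (1) it was 10 without a filter, 6 by DESeq2, 0 by limma, 7 with the cluster as a factor, 3 without 3 libraries, 7 without 4, and 0 to 2 with each library left out. For shDis3 against shExosc10 (2) it was 179 without a filter, 49 by DESeq2, 0 by limma, 1 with the 8 libraries alone or tested against a log2 fold change of 0.5, 617 without 3 libraries, 466 without 4, and 1 to 2 with each library left out. Shared calls of the knockdowns (0) were 5 without a filter, 2 by DESeq2, 2 without 3 libraries, 4 without 4, and 0 to 1 with each library left out. The correlation of their fold changes (0.396) was -0.242, -0.182, -0.279, -0.391, 0.000453 and 0.0487 with the controls split 2 and 2, as the parts no longer share libraries.

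With the replicate number as a block, the counts were 0, 1 and 1 in the 3 comparisons in the order above. Correlations of the deviations of same-numbered libraries ran from -0.47 to 0.77 and not every library correlated best with its own number. Replicates 2 of shLuc and shDis3 were each other's best partners (0.77). The deviations are from group means that include the libraries standing apart, so a pairing by number is neither shown nor excluded. Under the block Ccng1 in shDis3 against shLuc stood at 0.10, Sptb and Hist2h2aa1 in shExosc10 against shLuc at 0.01 each, and protein-coding genes in shDis3 against shExosc10 at a mean of -0.12.

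Dis3 in shDis3 against shLuc (-1.78) passed the threshold under RLE factors (-1.81), upper-quartile factors (-1.77), no filter (-1.77), a 5 CPM filter (-1.80), DESeq2 (-1.81), protein-coding genes only (-1.80), the robust estimate (-1.78), the cluster factor (-1.88), and without 3 (-1.85) or 4 libraries (-2.10). With each library left out it ran from -1.97 to -1.62. Exosc10 in shExosc10 against shLuc was -1.69 by limma, no longer past the threshold, and -1.97 to -1.74 with each library left out, missing the threshold without shExosc10 replicate 2 or 3. In shDis3 against shExosc10, Dis3 (-1.90) was no longer past the threshold by limma (-1.41), with the 8 libraries alone (-1.91), with the replicate block (-1.93) or tested against a log2 fold change of 0.5 (-1.90). It was -2.11 to -1.71 with each library left out and missed the threshold without shDis3 replicate 1 or 3 or shExosc10 replicate 3. Exosc10 (2.11) missed it by limma (2.08).

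With the cluster as a factor, signs turned in shDis3 against shLuc for Ccng1 (0.63), Cd24a (0.03), Sptb (0.45), Mpo (-0.08), Elane (-0.32) and Cd34 (-0.21). They turned in shExosc10 against shLuc for Zfpm1 (0.12), Sptb (0.10) and Hist1h1c (-0.11), and in shDis3 against shExosc10 for Itgb3 (-0.43), Gapdh (0.24), Eno1 (0.19), Myb (-0.22), Ccng1 (0.45), Sptb (0.35) and Lyz2 (-0.19). Mean log2 fold changes of lists turned in shDis3 against shLuc for heme synthesis (0.18), red cell genes (0.40), stem genes (-0.20), granulocyte (-0.22), macrophage (-0.16) and endothelial markers (-0.05) and ribosome biogenesis (-0.03), and in shExosc10 against shLuc for histone genes (-0.10), erythroid transcription factors (0.02) and stem genes (0.01). In shDis3 against shExosc10 they turned for histone genes (0.29), heme synthesis (0.19), red cell genes (0.05), stem genes (-0.21), granulocyte (-0.23), macrophage (-0.04), megakaryocyte (-0.29) and endothelial markers (-0.07), ribosomal protein genes (0.09), glycolysis and hypoxia (0.11), oxidative phosphorylation (0.10), long non-coding RNA (0.29) and snoRNAs (0.59). Of these, the calls in the turned direction were for heme synthesis, red cell, stem and granulocyte lists in shDis3 against shLuc, for histone genes in shExosc10 against shLuc, and for histone, heme synthesis, stem, granulocyte, megakaryocyte, ribosomal protein and oxidative phosphorylation lists and snoRNAs in shDis3 against shExosc10. None of these was called with an estimated correlation in that fit (adjusted p at least 0.543).

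Calls were lost with the sign kept in these fits. With the cluster as a factor these were, in shDis3 against shLuc, structured small RNAs (adjusted p = 0.241), snoRNAs and scaRNAs (0.534), megakaryocyte markers (0.84), glycolysis and hypoxia (0.241), the snoRNA class (0.0729) and snRNAs (0.204). In shExosc10 against shLuc they were the immediate early list (0.158) and the erythropoietin and STAT5 response (0.115). In shDis3 against shExosc10 they were ATF4 targets (0.608), protein-coding genes (0.772) and processed pseudogenes (0.20). Without 3 libraries they were ribosome biogenesis in shDis3 against shLuc (0.180), the immediate early list (0.197), the erythropoietin list (0.204), protein-coding genes (0.306) and long non-coding RNA (0.123) in shExosc10 against shLuc, and processed pseudogenes in shDis3 against shExosc10 (0.161). Without 4 they were red cell genes in shDis3 against shLuc (0.064), erythroid transcription factors (0.81), the immediate early and erythropoietin lists (0.11 each), protein-coding genes (0.21) and long non-coding RNA (0.071) in shExosc10 against shLuc. In shDis3 against shExosc10 they were ribosomal protein genes (0.051), oxidative phosphorylation (0.19), protein-coding genes (0.46) and snoRNAs (0.054). The block ended the calls of endothelial markers in shDis3 against shLuc (0.060), ATF4 targets (0.054), protein-coding genes (0.16) and long non-coding RNA (0.16) in shExosc10 against shLuc, and long non-coding RNA in shDis3 against shExosc10 (0.14). RLE factors ended that of protein-coding genes in shExosc10 against shLuc (0.061). With an estimated correlation or fry all list and class calls were lost, except that of protein-coding genes in shDis3 against shExosc10 with an estimated correlation.

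Without 3 libraries signs turned in shExosc10 against shLuc for Zfpm1 (0.11), Sptb (0.09), Hist1h1c (-0.09), histone genes (-0.09), erythroid transcription factors (0.02) and stem genes (0.14). Without 4 they turned for Nrgn (0.02) and ribosome biogenesis (-0.10) in shDis3 against shLuc, for Zfpm1 (0.08), Sptb (0.06), Hist1h1c (-0.12), Jak2 (-0.02), histone genes (-0.13) and stem genes (0.09) in shExosc10 against shLuc, and for long non-coding RNA (0.28) and processed pseudogenes (0.22) in shDis3 against shExosc10. Values near 0 also turned for Ccng1 under upper-quartile factors (0.02) and limma (0.35), Sptb in shExosc10 against shLuc under upper-quartile factors (0.00), and Hist2h2aa1 under upper-quartile factors (0.02), no filter (0.00), a 5 CPM filter (0.01), limma (0.12) and protein-coding genes only (0.00).

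With each library left out, the sign turned somewhere in these ranges. In shDis3 against shLuc they were -0.41 to 0.06 for Nrgn, -0.26 to 0.19 for Ccng1, -0.06 to 0.61 for Hba-a1, -0.15 to 0.76 for Hbb-bs, -0.31 to 0.03 for red cell genes, -0.02 to 0.98 for endothelial markers and -0.03 to 0.24 for ribosome biogenesis. In shExosc10 against shLuc they were -0.05 to 0.24 for Dis3, -0.23 to 0.26 for Sptb, -0.18 to 0.33 for Hist2h2aa1, -0.11 to 0.35 for Hist1h1c, -0.06 to 0.18 for Jak2, -0.29 to 0.02 for glycolysis and hypoxia, -0.06 to 0.39 for histone genes, -0.58 to 0.45 for stem genes, -0.03 to 0.18 for protein-coding genes and -0.07 to 0.75 for long non-coding RNA. In shDis3 against shExosc10 they were -0.08 to 0.25 for Lyz2, -1.69 to 0.14 for long non-coding RNA, -0.47 to 0.10 for protein-coding genes and -1.21 to 0.01 for processed pseudogenes. Of 39 called list results, 37 kept sign and call with the block, 39 with RLE factors, and 0 kept the call with an estimated correlation or fry.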

Other observations

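All tests in this part were chosen after the result was seen. Beyond the lists, genes chosen after their values were seen were examined with the cluster of libraries as a factor. Inka2 (chromosome 3, 105704599 to 105720842), which was not on the p53 list, was the only gene besides Dis3 called in shDis3 against shLuc in that fit (log2 fold change 2.05, SE 0.27, adjusted p = 0.00433), against 0.94 in the 12 libraries without the factor. The list members Eda2r (1.82), Cdkn1a (1.32), Phlda3 (1.33), Psrc1 (1.19) and Ak1 (2.10) each had an adjusted p = 0.136 there and did not pass. Cdkn1a, which encodes the cell cycle inhibitor p21, measured 78.74 ± 39.43 CPM in shDis3 and 45.79 ± 19.62 in shLuc. That fit takes the shDis3 effect against shLuc from shDis3 replicate 3 over shLuc replicate 4. It also takes it from shDis3 replicate 4 over shExosc10 replicate 1, joined to shExosc10 over shLuc in the largest cluster. These pairs are therefore no separate test of the genes named. In both pairs the clustered histone genes were higher, with medians of 0.11 (51 of 66) and 0.25 (61 of 66), and heme genes with medians of 0.16 (19 of 23) and 0.13 (17 of 23).

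Against shLuc, a few genes were higher in shExosc10 in some fits. With the cluster of libraries as a factor, the called genes besides Exosc10 were Rab1a (1.88, adjusted p = 0.000499), a GTPase of vesicle transport, Serinc3 (1.06, adjusted p = 0.0171), the water channel Aqp1 (1.56, adjusted p = 0.00788), Cpeb4 (1.21, adjusted p = 0.00788), Tmcc2 (2.04, adjusted p = 0.0207) and Sfrp4, all chosen after their values were seen. DESeq2 also called Rab1a, Serinc3 and Sfrp4, with Chp1, Mid1ip1 and Exosc10. Rab1a (chromosome 11, 20201432 to 20226856) measured 18.64, 18.16, 17.84 and 59.81 CPM in shLuc replicates 1 to 4 and 65.38 to 103.6 in the 8 other libraries. It was the only gene at least 2-fold lower in shLuc replicates 1 to 3 than in each of the other 9 libraries, and 8 of the 220 sets of 3 libraries had as many such genes. Transcripts of both sexes were counted in all 12 libraries, with Xist at 37.1 to 599.9 and Ddx3y at 22.2 to 74.0 CPM before TMM.

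The counts of called genes were set against other splits of the same 8 libraries. For shDis3 against shLuc the real count was 0, so all 35 of 35 splits gave as many and the count of calls tests nothing (highest other 1453, for shLuc replicates 1 to 3 with shDis3 replicate 2 against the rest). At an unadjusted p under 0.05, 16 of 35 splits gave at least the real 719 genes (highest other 5128), so chance cannot be excluded. Splits that call many times the real count point to a structure of the samples other than the shRNA. With the cluster of libraries as a factor, 7 of 34 splits gave as many as the real 2 genes (highest other 217), so chance cannot be excluded. For shExosc10 against shLuc, 1 of 35 splits gave as many as the real 1 gene (highest other 0), but that gene is the target, so the count restates the knockdown. At an unadjusted p under 0.05, 19 of 35 splits gave at least the real 371 genes (highest other 1511), so chance cannot be excluded for other genes. With the cluster as a factor 3 of 35 gave as many as the real 7 (highest other 33), so chance cannot be excluded for Rab1a and the genes beside it. For shDis3 against shExosc10, 2 of 35 splits gave as many as the real 2 genes, both of them targets (highest other 1213, for shDis3 replicates 1, 3 and 4 with shExosc10 replicate 1), and with the cluster as a factor 3 of 34 (highest other 3), so chance cannot be excluded by this count in either. At an unadjusted p under 0.05, 13 of 35 splits gave at least the real 1056 genes (highest other 5383). The splits with 1453 and 1213 calls both set the libraries of the largest cluster, together with shDis3 replicate 2, against the rest.

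Without the 3 libraries far from their groups only 10 splits of 6 libraries exist, too few for a share under 0.05. The real counts and the highest of the others there were 772 and 1971 for shDis3 against shLuc (2 of 10 splits as large), 3 and 0 for shExosc10 against shLuc (1 of 10), and 617 and 4 for shDis3 against shExosc10 (1 of 10). The 545 genes called higher in shDis3 than in shLuc in the 9 libraries left were higher in 45.7% of cases in shDis3 replicate 4 than in shExosc10 replicate 1 (54.3% of all genes), and in 23.5% of cases in shDis3 replicate 3 than in shLuc replicate 4 (45.2% of all genes). For the 227 called lower these shares were 42.3% and 56.4%. In those 9 libraries Itgb3 (2.47, adjusted p = 0.000233) and Cd34 (2.30, adjusted p = 0.00026), the latter chosen after its values were seen, were called higher in shDis3, while with the cluster of libraries as a factor Cd34 stood at -0.21. The left-out shLuc replicate 4 held 154 CPM of Itgb3 (other shLuc libraries 17.58 to 25.27) and 64.5 CPM of Cd34 (others 6.23 to 8.62). These calls therefore depend on the choice of libraries.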
